A study of Arabidopsis thaliana with 9 samples.

How the data were processed

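RNA sequencing was analysed for 9 libraries of whole Arabidopsis thaliana seedlings, 3 each of WT, SR45a-1a-OE and sr45a, all 2 weeks old and all heated at 45 °C for 3 h. Per the labels' protocols, the authors isolated total RNA with Trizol, sequenced 150-bp paired-end reads on a NovaSeq instrument and trimmed them with fastp, keeping reads of at least 36 bp. The aligner, the counting program, the genome build and the annotation were not given in the sources used here. Whether the numbers 1 to 3 mark separate plant lines or repeated samples of 1 line was not given either.

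Per the file headers, the deposited gene tables hold a count and an FPKM (fragments scaled to transcript length and library size) for 27218 genes in each library, and the deposited transcript tables hold an estimated count and an FPKM for 68898 transcripts. The deposited gene counts were whole numbers. The ratio of count to FPKM gave the same length for a gene in every library, with a largest relative SD of 5.9e-05, so the authors made both columns from 1 set of counts. The deposited transcript estimates summed to 3.786–3.871 times the gene counts of the same library. In genes with a single transcript and at least 500 counts the median ratio was 3.905, so transcript estimates are on a larger scale than fragments and were used for shares and relative differences. Of the transcripts 47173 carried a gene identifier and 21725 did not. Gene coordinates in the deposited tables equalled TAIR10.1 at both ends for 26961 of the 26968 loci compared, and symbols and descriptions were matched by locus to that annotation. The 43 genes with no Arabidopsis locus identifier were kept in the fits but named nowhere.

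Depth was 18036195 to 21864604 gene counts and 69441431 to 84634157 transcript estimate units per library. CPM are these counts scaled by library total and TMM factor. TMM factors lay between 0.935 and 1.048. The 10 most abundant genes took 7.15–10.3% of the counts, chloroplast genes 0.04–0.07% and mitochondrial genes 0.05–0.16%. Taken over genes together, counting error was small beside the spread between replicates: the chi-square per gene between libraries of 1 group was 5.34 to 40.9. For genes with few counts, counting error can be as large as that spread or larger.

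Groups were taken from the labels. The main test for genes was edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by genotype (minimum count 10, minimum total 15), a quasi-likelihood fit of all 9 libraries with 1 coefficient per genotype, F tests for the 3 pairs of genotypes and a Benjamini-Hochberg adjusted p under 0.05. It tested 20103 genes. The same fit on rounded estimates tested 35982 transcripts that have a gene identifier. Usage was tested with diffSpliceDGE and gene-level Simes p-values for the 7888 genes with 2 or more tested transcripts. Standard errors of the fold changes were derived from the F statistics. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided and adjusted over 15 lists. The 15 lists hold 326 genes: heat shock factors and regulators, small heat shock proteins, large chaperones, SR proteins, other splicing factors, detoxification, abscisic acid and dehydration, unfolded protein response, photosynthesis, defence, flavonoids, senescence, clock, and markers of roots and of flowering. The targeted gene is in none of them. The overlap of the comparisons with WT was set beside 20 simulations of groups with no difference from the same WT libraries and beside independent lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

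The groups, tests, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule named SR45a, and in each comparison with WT the 8 genes with the largest rise and the 8 with the largest fall that passed, did not overlap between groups, reached a mean of 5 CPM in the higher group and had a symbol or a description. It took 4 and 4 for SR45a-1a-OE against sr45a. From each list it named the 3 called members with the smallest p or, where none was called, the 2 most abundant as values; for SR45a-1a-OE against sr45a only lists past the camera threshold were used. For usage it named the 6 genes with the smallest p in which a transcript moved by at least 10 percentage points.

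The alternatives were DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, only the 6 libraries compared, the replicate number as a block, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), an additional log2 fold change of at least 1, an estimated inter-gene correlation for camera, a transcript share of at least 5% and limma diffSplice on voom values for usage, and leaving out each library in turn. Where a library was left out, its group kept 2, and the spread was pooled over all groups. Chosen after the data were seen were a transcript fit that includes transcripts with no gene, fits on estimates divided by 4, lists of seed reserve and phosphate genes, a window around SR45a and tests of process terms from the annotation.

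The steps were tested on simulated data made from the levels and spread of all 9 libraries, with known changes put into SR45a-1a-OE and tested against WT. At 2-fold and 4-fold, edgeR recovered 75% and 98% of changed genes with 12 false calls, and DESeq2 77% and 97% with 35 false calls. For transcripts edgeR recovered 3% at 4-fold and 47% at 32-fold with 1 false call, and DESeq2 28% and 80% with 204 false calls. Simulated switches of usage were recovered in 0%, 13.7% and 55.2% of 3 separate classes of 120, 51 and 29 genes, with ratios between transcript levels that begin at 1, 4 and 16, with 3 false calls. A list shifted by 0.5 was recovered and 0 other lists were called, but the simulated genes varied independently of each other. In the data the estimated inter-gene correlation of a list reached 0.55. The simulation therefore cannot show how many false list calls correlated genes give. Left out were expected responses to heat, since no library was unheated, and splice junctions, which need the reads.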

Results

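The data are RNA sequencing counts from 9 libraries of Arabidopsis thaliana seedlings, grown for 2 weeks under long days and held at 45 °C for 3 h before harvest. Wild type (WT), an SR45a-1a overexpressor (SR45a-1a-OE) and an sr45a mutant gave 3 libraries each. SR45a (AT1G07350) encodes a serine/arginine-rich protein with an RNA recognition motif, a class of proteins that act in pre-mRNA splicing. The series asks how splicing of SR45a itself bears on tolerance of heat. The 3 comparisons between the genotypes ask which heated transcripts differ when SR45a is raised or lost. All 9 libraries were heated, so the response to heat itself was not measurable. The gene counts summed to 21833182, 21610270 and 21864604 in WT replicates 1 to 3, to 21522098, 21584219 and 21793346 in SR45a-1a-OE and to 21638530, 18036195 and 20030269 in sr45a. Between 23042 and 23263 genes had a count in a library, and 20103 genes were tested. Levels are given in CPM, the count of a gene scaled to a common library size, as mean ± SD with n = 3 libraries per group. Fold changes are log2 values with their standard error (SE), adjusted p-values come from edgeR quasi-likelihood tests with the Benjamini-Hochberg correction, and coordinates are those of TAIR10.1. The p-values measure the spread between these libraries, which may be technical in part, since the labels do not say what separates the replicates. SR45a-1a-OE replicate 3 and sr45a replicate 3 stood apart from their groups on the first principal component, which held 36.6% of the variance. Their coordinates on it were 16.21 against 48.28 and 47.02 for the other two SR45a-1a-OE libraries, and 4.7 against −25.35 and −22.24 for the other two sr45a libraries.

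SR45a followed the labels of all 9 libraries. The gene lies on the minus strand of chromosome 1 at 2257384–2260187. Its transcripts reached 418 ± 15.97 CPM in heated WT, 1094 ± 81.6 CPM in SR45a-1a-OE and 4.57 ± 2.68 CPM in sr45a, which is 1.09% of the WT level. SR45a rose in SR45a-1a-OE by a log2 fold change of 1.39 (SE 0.27, adjusted p = 0.00816), a 2.62-fold higher level. It fell in sr45a with a log2 fold change of −6.52 (SE 0.34, adjusted p = 3.4e-06). SR45a-1a-OE exceeded sr45a by 7.91 (SE 0.36, adjusted p = 6.75e-07). On the deposited FPKM scale the same gene stood at 213 ± 11.6 in WT, 537 ± 29.1 in SR45a-1a-OE and 2.34 ± 1.36 in sr45a.

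**Figure D1:**
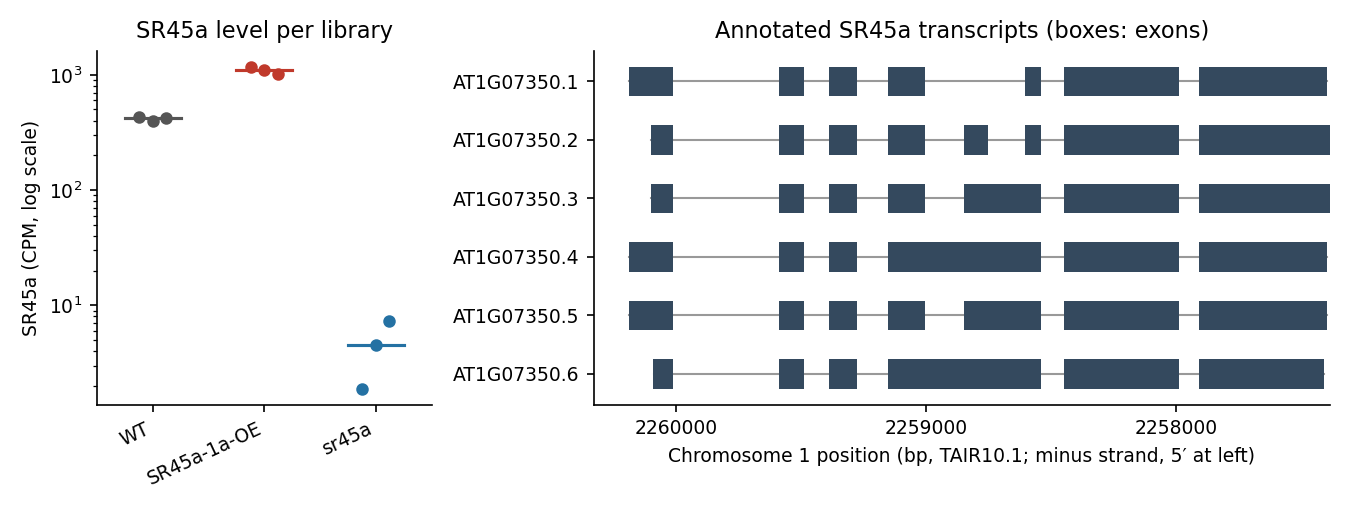
SR45a in each library and its annotated transcripts. The left panel plots SR45a CPM on a log axis, with a point per library and a line at each group mean (418 in WT, 1094 in SR45a-1a-OE, 4.57 in sr45a). The right panel draws the exons of the 6 annotated transcripts to scale along chromosome 1 (TAIR10.1, base pairs), with the 5′ end at the left.

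AT1G07350.1 took nearly all of the estimate summed over the 6 annotated SR45a transcripts in both genotypes that express the gene. Its share of that sum was 93.9 ± 0.725% in WT and 95.8 ± 0.721% in SR45a-1a-OE. In FPKM it stood at 139 ± 7.48 in WT and 303 ± 17.1 in SR45a-1a-OE, against 213 and 537 for the whole gene. No other of the 6 averaged above 4.53 FPKM. Gene and transcript FPKM use different lengths, so the estimates were also set beside the gene counts. AT1G07350.1 had 19575 estimate units against 9768 gene counts in WT replicate 1, and 39794 against 23590 in SR45a-1a-OE replicate 1. In genes with a single transcript the median ratio was 3.905. Part of the gene's signal thus appears to lie outside these 6 transcripts. The shares leave it out and do not describe the whole gene. AT1G07350.1 has a coding length of 1149 bp and lacks the 96-bp exon at 2258750–2258845 that AT1G07350.2 includes; the coding length of AT1G07350.2 is 390 bp. AT1G07350.2 took 0.140 ± 0.124% in WT and 1.48 ± 0.943% in SR45a-1a-OE. AT1G07350.3 and AT1G07350.5 share a 307-bp exon at 2258539–2258845. AT1G07350.3 took 1.92 ± 1.36% in WT and 0.296 ± 0.502% in SR45a-1a-OE, and AT1G07350.5 took 0.239 ± 0.295% and 1.49 ± 0.183%. AT1G07350.4 and AT1G07350.6 share a 614-bp exon at 2258539–2259152. AT1G07350.4 took 2.02 ± 1.39% in WT and 0.743 ± 0.870% in SR45a-1a-OE, and AT1G07350.6 took 1.82 ± 1.42% and 0.225 ± 0.165%. In sr45a the share of AT1G07350.1 was 65.8 ± 34.5%, with 117, 55 and 150 estimate units in the 3 libraries against 17671 or more in WT, so the split between transcripts was not measurable at this depth. The level of AT1G07350.1 fell in sr45a, with a log2 fold change of −7.33 (SE 0.38, adjusted p = 0.00165). In SR45a-1a-OE its log2 fold change of 1.16 did not pass (SE 0.29, adjusted p = 0.192), and neither did those of the other 5 transcripts, from −1.87 for AT1G07350.6 to 4.53 for AT1G07350.2, with adjusted p of 0.357 or more. The labels do not say which of these transcripts SR45a-1a is.

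Of the 3 comparisons SR45a-1a-OE against equally heated WT called the most genes. In SR45a-1a-OE 1358 genes rose and 1726 fell, 15.34% of those tested. Of these 3084 genes 680 changed at least 2-fold, 316 upward and 364 downward. The genes whose groups did not overlap numbered 7146, or 35.55%, where chance gives 10%. The heat shock factor gene HSFA7B rose from 1.43 ± 0.0777 to 8.002 ± 3.64 CPM (log2 fold change 2.48, SE 0.36, adjusted p = 0.00335), and ELIP2, which encodes an early light-induced protein, rose from 0.791 ± 0.12 to 6.31 ± 2.24 CPM (2.99, SE 0.32, adjusted p = 0.00138). A pyruvate decarboxylase gene (AT4G33070) rose by 2.24, the cullin gene CUL2 by 2.59 and the pentatricopeptide repeat gene AT1G33350 by 2.25. For these 5 genes sr45a replicate 3 was above SR45a-1a-OE replicate 3, at 3.98 against 3.804 CPM for HSFA7B and 14.03 against 7.004 CPM for CUL2. The largest rise among called genes averaging 5 CPM or more was that of the non-coding RNA AT2G01422 (chromosome 2, 183940–184734), from 0.152 ± 0.0277 to 25.1 ± 1.44 CPM. The non-coding RNA AT3G05945 (4.02, SE 0.34) and the hypothetical protein gene AT1G75945 (4.89, SE 0.40) rose as well.

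Among the 8 genes of at least 5 CPM that fell most in SR45a-1a-OE was BRU6, of the GH3 family of auxin-conjugating enzymes. It fell from 77.4 ± 1.71 to 10.4 ± 6.82 CPM (log2 fold change −2.90, SE 0.38, adjusted p = 0.00271). The expansin gene EXPA5 fell from 25.01 ± 5.26 to 4.40 ± 4.04 CPM, and the arabinogalactan protein gene FLA1 from 58.2 ± 6.42 to 15.1 ± 5.80 CPM. The same lower levels appeared in sr45a replicate 3, with almost no SR45a: 26.2 CPM for BRU6, 7.06 for EXPA5 and 28.8 for FLA1, against 18.23, 9.05 and 21.8 in SR45a-1a-OE replicate 3. ESM1, an epithiospecifier modifier gene, fell from 411 ± 37.3 to 93.8 ± 47.4 CPM (−2.13, SE 0.34, adjusted p = 0.00433; 164 CPM in sr45a replicate 3), and the beta-glucosidase gene BGLU28 fell by a log2 fold change of −2.17. ADT4, an arogenate dehydratase gene of phenylalanine synthesis, fell with a log2 fold change of −1.97 (SE 0.16, adjusted p = 2.15e-04), and AT1G70985, a hydroxyproline-rich glycoprotein gene, with −2.16. The expressed protein gene AT3G01345 (chromosome 3, 129138–130749) went from 325 ± 10.8 to 0.816 ± 0.213 CPM, a log2 fold change of −8.62 (SE 0.28, adjusted p = 1.15e-08). EXPA5 alone of these 16 genes lost its call under an alternative, without SR45a-1a-OE replicate 1 (adjusted p = 0.0661). The total of 3084 became 1410, 1060 and 1836 genes without WT replicate 1, 2 or 3, and 975 without SR45a-1a-OE replicate 1; without replicate 3, which stood apart, it was 3944.

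Of the heat shock genes, 6 factors or regulators and 10 small heat shock protein genes rose in SR45a-1a-OE against equally heated WT, while large chaperones went both ways. Of 21 measured heat shock factors and heat-response regulators 6 rose, none fell and 15 did not pass (6 when adjusted over the list alone), with a list median of 0.27. HSFA3 rose from 44.2 ± 1.70 to 96.2 ± 4.13 CPM (log2 fold change 1.12, SE 0.16, adjusted p = 0.00335) and HSFA1E from 8.58 ± 0.509 to 19.6 ± 3.61 CPM (1.19, SE 0.21, adjusted p = 0.00605). Small heat shock proteins bind unfolding proteins, and 10 of their 18 genes rose (13 when adjusted over the list alone), with a median of 0.61 and none lower. HSP17.8 rose from 443 ± 32.4 to 1293 ± 479 CPM (1.55, SE 0.26, adjusted p = 0.00511), the plastid HSP21 from 1438 ± 182 to 3346 ± 751 CPM (1.22, SE 0.22, adjusted p = 0.00667) and HSP17.4 from 246 ± 11.2 to 447 ± 103 CPM. These 3 were higher in sr45a replicate 3, at 1000, 3227 and 456 CPM, than in SR45a-1a-OE replicate 3, at 794, 2490 and 331 CPM, so their level did not follow that of SR45a across libraries. HSFA3 was at 70.3 CPM in sr45a replicate 3 and 91.4 CPM or more in SR45a-1a-OE. HSP18.2 alone held 2.27–2.94% of all counts in SR45a-1a-OE and 1.52–1.86% in WT. Large chaperones went both ways, 4 up and 3 down of 36 (the same numbers when adjusted over the list alone). HSP90.3 fell by a log2 fold change of −1.06 (SE 0.17, adjusted p = 0.0046), HSP70-2 by −1.04 and HSP90.6 by −0.54; the first 2 have close paralogs that can exchange reads. In the competitive list test (camera) the heat shock factors passed with adjusted p = 4.04e-04, though with adjusted p = 0.572 with an estimated correlation. Small heat shock proteins passed with adjusted p = 4.3e-05, and gave adjusted p = 0.772 with an estimated correlation; large chaperones did not pass (adjusted p = 0.856). With the unfolded protein response 3 lists passed in this comparison, and splits that mix the genotypes gave up to 7. A true difference partly remains in such splits, so here and below their counts are not values for groups with no difference.

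**Figure D2:**
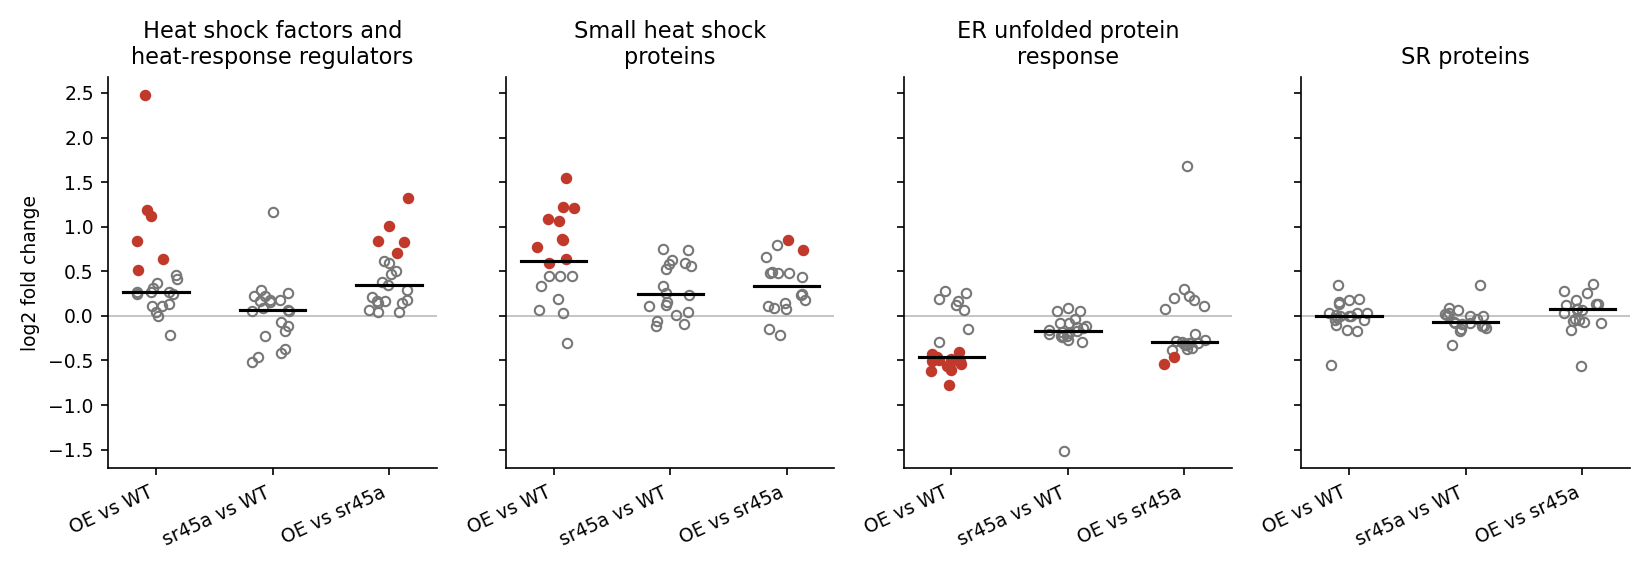
Log2 fold changes of the members of 4 gene lists in the 3 comparisons. Each point is a gene, filled red when past the threshold and open when not, and the line marks the list median, such as 0.61 for the small heat shock proteins and −0.47 for the unfolded protein response in SR45a-1a-OE against WT.

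Chaperones of the endoplasmic reticulum moved against the small heat shock proteins. Of 21 genes of the unfolded protein response 13 fell in SR45a-1a-OE and none rose (14 fell when adjusted over the list alone), with a median of −0.47. BIP2, which has the close paralog BIP1, fell from 1544 ± 45.0 to 901 ± 79.6 CPM (log2 fold change −0.78, SE 0.13, adjusted p = 0.0046). The disulfide isomerase gene PDIL2-1 fell from 308 ± 11.6 to 200.3 ± 18.17 CPM (−0.62, SE 0.12, adjusted p = 0.00839; 217 CPM in sr45a replicate 3), and the calreticulin gene CRT1A from 930.3 ± 16.97 to 631 ± 60.2 CPM (−0.56, SE 0.11). The list passed in camera (adjusted p = 7.99e-05; adjusted p = 0.572 with an estimated correlation).

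No SR protein gene passed in SR45a-1a-OE. edgeR called 0 of the 19 SR genes, over all genes and when adjusted over the list alone, with a median of −0.0044 where the test pointed up. SR30 stood at 589 ± 71.5 CPM against 461 ± 8.29 in WT (log2 fold change 0.35, adjusted p = 0.0588) and SR34 at a log2 fold change of −0.05 (adjusted p = 0.809). Of 21 other splicing factor and cap-binding genes 3 passed (3 when adjusted over the list alone). U2AF35A rose by 0.37 (SE 0.11, adjusted p = 0.0405), the pre-mRNA splicing factor gene STA1 by 0.61 (SE 0.18, adjusted p = 0.0417), and the glycine-rich RNA-binding protein gene GRP8 fell with −0.45 (SE 0.11, adjusted p = 0.0187). Neither list passed in camera (adjusted p = 0.856 for both).

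The remaining lists held scattered calls in SR45a-1a-OE and none passed in camera, with adjusted p from 0.142 to 0.934. Of 24 abscisic acid and dehydration genes 5 rose and 1 fell (8 and 2 when adjusted over the list alone), among them KIN1 (log2 fold change 1.12, SE 0.14, adjusted p = 0.00251), LTI30 (1.14) and RD29B (1.28). Of 27 reactive oxygen and detoxification genes 7 rose and 2 fell (7 and 3 when adjusted over the list alone): ZAT12 rose by 1.38, GSTU19 by 0.96, and the catalase gene CAT3 fell from 1036 ± 50.8 to 562 ± 49.8 CPM. Jasmonate synthesis genes gave the 3 calls among 23 defence genes, all downward (3 when adjusted over the list alone): LOX2 fell from 69.6 ± 3.61 to 20.4 ± 11.4 CPM, AOS by −0.72 and OPR3 by −0.53. The defence median was 0.12 where the mean (−0.0093) and the test pointed down. Of 33 photosynthesis genes 4 rose and 1 fell (5 when adjusted over the list alone), with GAPA1 at 0.70, PSBO2 at 0.53 and PSBS at 0.45; their median was −0.03 where the mean of 0.063 and the test pointed up. The flavonol synthase gene FLS1 (0.93) and its regulator MYB12 (0.78) rose among 6 flavonoid genes (3 when adjusted over the list alone). LHY, a morning clock gene, rose from 3.51 ± 0.538 to 10.5 ± 3.23 CPM, BOA rose by 0.46 and LNK2 fell with −0.44 among 19 clock genes (4 when adjusted over the list alone). SAG21 (0.63) and NYE1 (0.43) rose and SEN1 (−0.85) fell among 10 senescence genes (3 when adjusted over the list alone). Root markers split, with PHT1.1 (−0.75; it has a near-identical paralog) and PRP3 (−0.95) lower and THAS (0.76) higher among 15 (5 when adjusted over the list alone), and their median of 0.08 lay above 0 where the test pointed down. Of 3 measured flowering genes SOC1 rose by 0.99 (1 when adjusted over the list alone). Of the 39 called list genes named for this comparison 22 stayed past the threshold in every alternative. The other 17 lost it at least once, with adjusted p between 0.0503 and 0.163, namely GRP8, U2AF35A, STA1, CRT1A, GAPA1, PSBO2, PSBS, AOS, OPR3, MYB12, SEN1, NYE1, LNK2, BOA, PRP3, THAS and SOC1.

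Far fewer genes passed the threshold in sr45a against heated WT than in SR45a-1a-OE. At an unadjusted edgeR p under 0.05 the numbers were 3159 in sr45a and 6430 in SR45a-1a-OE. Among called genes averaging 5 CPM or more in the higher group, 4 of the 8 largest rises in sr45a were in seed storage and glyoxylate cycle genes. In sr45a 173 genes rose and 153 fell against WT, 1.62% of those tested, and 121 and 58 of them at least 2-fold. Groups did not overlap for 4846 genes, or 24.11%, where chance gives 10%. The seed storage globulin genes CRA1 and CRC went from 0.532 ± 0.102 to 12.8 ± 2.47 CPM and from 0.0756 ± 0.0253 to 12.2 ± 5.03 CPM. The glyoxylate cycle genes ICL (isocitrate lyase) and MLS (malate synthase) rose from 14.0 ± 4.08 to 173 ± 74.5 CPM (log2 fold change 3.63, SE 0.38, adjusted p = 9.63e-04) and from 0.947 ± 0.386 to 9.90 ± 2.87 CPM (3.38, SE 0.43, adjusted p = 0.0028). The glutathione transferase gene GSTF6 rose by 3.08 (SE 0.23, adjusted p = 8.27e-05) and AT2G47780, annotated as a rubber elongation factor protein gene, by 2.82. AT3G05945 rose by 4.12, and AT5G36790, whose near-identical copy makes its count uncertain, by 3.02.

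Genes that plants raise when phosphate is scarce made up 4 of the 8 largest falls in sr45a within the same limit of 5 CPM. MGD3, a galactolipid synthase gene, fell from 12.8 ± 2.501 to 1.93 ± 0.906 CPM (log2 fold change −2.72, SE 0.31, adjusted p = 0.00144). The non-coding RNA IPS1 fell from 7.95 ± 3.28 to 1.36 ± 0.667 CPM, the phosphatase gene PECP1 from 11.4 ± 4.66 to 2.07 ± 0.627 CPM and the pyrophosphatase gene PS2 from 31.2 ± 3.13 to 6.96 ± 2.37 CPM (−2.16, SE 0.26, adjusted p = 0.00201). AT3G01345, also low in SR45a-1a-OE, fell from 325 ± 10.8 to 3.74 ± 1.58 CPM (−6.43, SE 0.24, adjusted p = 1.14e-07). The hydrolase gene AT1G08310 (−2.22), which lies within 1 Mb of SR45a, the Spt5 gene AT2G34210 (−2.22) and MLO7 (−1.95) fell too. Root markers PHT1.1 and THAH fell alongside, by log2 fold changes of −0.68 and −1.02, but PHT1.1 is also annotated to the response to phosphate starvation. Calls ended for CRC without WT replicate 2 (adjusted p = 0.0508), AT5G36790 without WT replicate 1 or 2 (0.053 and 0.057), IPS1 without sr45a replicate 2 (0.054) and MLO7 without sr45a replicate 1 or 2 (0.059 and 0.062). The total of 326 genes became 137, 106 and 151 without WT replicate 1, 2 or 3, and 139, 137 and 215 without sr45a replicate 1, 2 or 3.

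**Figure D3:**
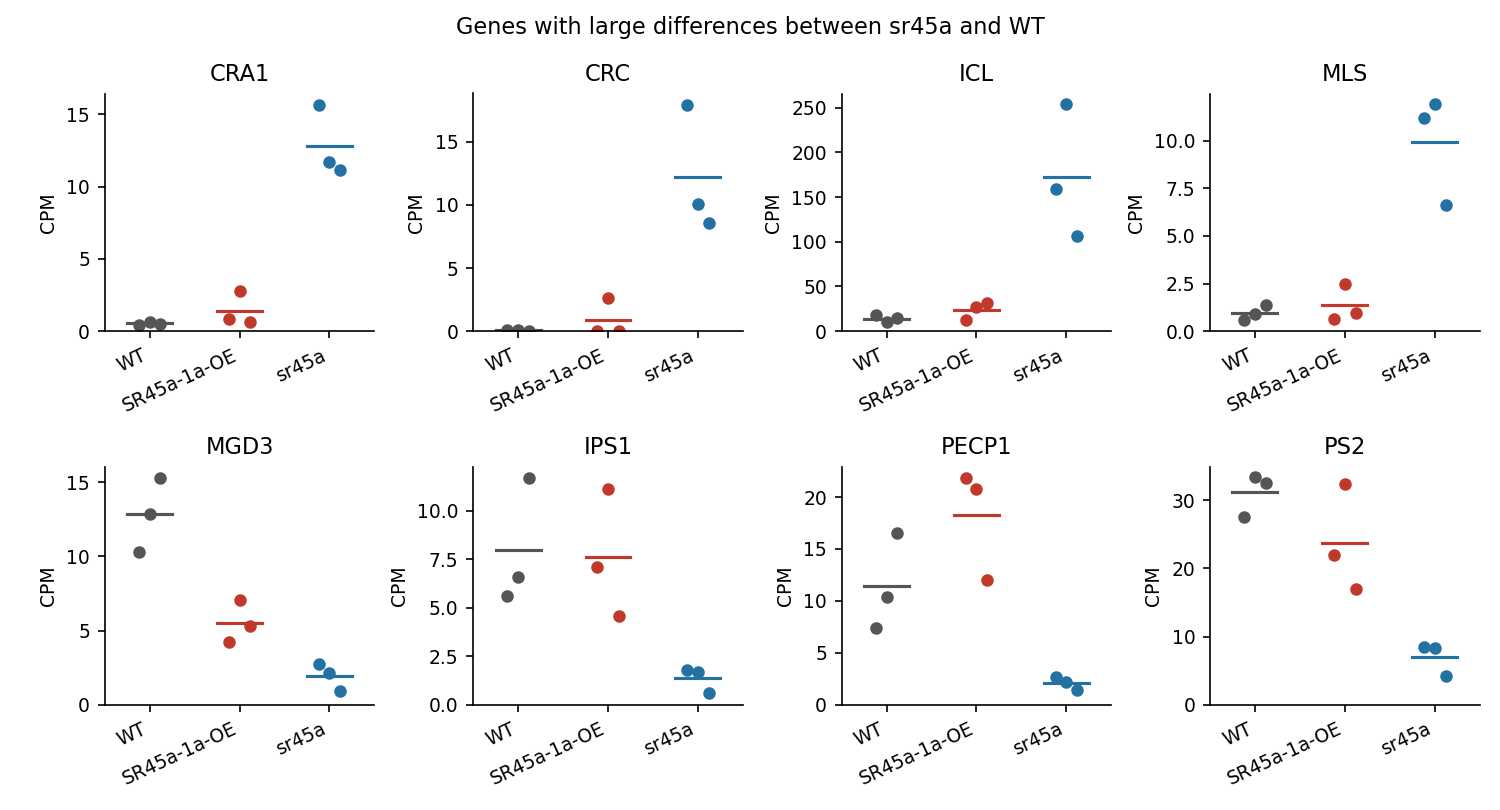
CPM per library of 8 genes among the largest changes in sr45a against WT (genes averaging 5 CPM or more in the higher group). Points are libraries and lines group means for the seed and glyoxylate genes CRA1, CRC, ICL and MLS and the phosphate-response genes MGD3, IPS1, PECP1 and PS2; ICL averages 173 CPM in sr45a, 14.0 in WT and 23.7 in SR45a-1a-OE.

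No single heat shock gene of the fixed lists passed in sr45a. edgeR called 0 of 21 heat shock factors and regulators and 0 of 36 large chaperones, also when adjusted over the list alone, with medians of 0.07 and 0.03. For the large chaperones the test pointed down, against the median and the mean of 0.0392. MBF1C had a log2 fold change of −0.17 (adjusted p = 0.786), HSFB1 one of 0.16 (0.703), HSP70-1 one of −0.14 (0.616) and ROF2 one of 0.08 (0.879). Small heat shock proteins gave 0 calls over all genes and 3 upward when adjusted over the list alone; HSP18.2 stood at 18436 ± 1679 CPM against 17135 ± 2111 in WT and HSP22.0 at a log2 fold change of 0.01. With 15 of the 18 values above 0 and a median of 0.25, that list passed in camera (adjusted p = 0.00524; adjusted p = 0.661 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.0842). Unfolded protein response genes passed downward (median −0.17, adjusted p = 0.00524; adjusted p = 0.661 with an estimated correlation) with 0 calls by either adjustment, BIP1 at −0.18 and HSP90.7 at −0.30. Other splicing factors passed downward as well (median −0.16, adjusted p = 0.00524; adjusted p = 0.162 with an estimated correlation). Of those 21 genes only GRP8 fell, from 299.7 to 199 ± 13.8 CPM (log2 fold change −0.59, SE 0.11, adjusted p = 0.02), and 5 fell when adjusted over the list alone. SR protein genes gave 0 calls of 19 by either adjustment, with a median of −0.07; SR30 was at 0.09 and SR34 at −0.11. Splits that mix the genotypes gave up to 3 lists, as many as passed here, but such splits are not groups with no difference. For the lists with 0 calls, the whole comparison held 3159 genes at an unadjusted p under 0.05 and 704 calls with DESeq2.

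The other lists did not pass in camera in sr45a, with adjusted p from 0.111 to 0.764. Of 27 detoxification genes 3 rose (3 and 1 lower when adjusted over the list alone): GSTU25 by 2.28 and GSTU24 by 2.03, which are close paralogs, and GSTU19 by 0.83. ABF2 fell with −0.65 among 24 abscisic acid genes, where 3 rose and 5 fell when adjusted over the list alone. PHT1.1 (−0.68) and THAH (−1.02, from 34.7 ± 2.62 to 17.2 ± 2.44 CPM) fell among 15 root markers (1 higher and 4 lower when adjusted over the list alone). edgeR called 0 of 33 photosynthesis, 23 defence, 6 flavonoid, 10 senescence, 19 clock and 3 flowering genes. Adjusted over the list alone, 1 flavonoid and 1 senescence gene rose and the other lists stayed at 0. Their most abundant members had log2 fold changes of 0.34 (RBCS1A) and 0.15 (LHCB1.3), −0.30 (PR4) and 0.06 (AOS), −0.09 (CHS) and 0.52 (FLS1), −0.29 (NYC1) and 0.32 (SAG21), −0.31 (PRR7) and −0.41 (GI), and −0.69 (SEP3) and 0.36 (SOC1). The photosynthesis median of −0.03 lay below 0 where the mean of 0.0232 and the test pointed up. All 7 list genes that changed in sr45a (GRP8, GSTU24, GSTU25, GSTU19, ABF2, PHT1.1 and THAH) lost the threshold in at least 1 alternative, with adjusted p up to 0.167.

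Setting SR45a-1a-OE directly against sr45a compares much with almost no SR45a. In SR45a-1a-OE 565 genes were higher and 894 lower than in sr45a, 7.26% of those tested; 141 and 344 of them differed at least 2-fold. From FPKM with limma the split was 372 higher and 977 lower (364 and 981 with the smaller pseudocount). Groups did not overlap for 5070 genes, or 25.22%, where chance gives 10%. EARLI1, a lipid-transfer protein gene, was at 1.91 ± 0.868 CPM in SR45a-1a-OE and 36.3 ± 12.9 CPM in sr45a (log2 fold change −4.23, SE 0.32, adjusted p = 8.5e-05). ICL was lower in SR45a-1a-OE (23.7 ± 10.02 CPM, −2.87), as were CRA1 (−3.16) and CRC (−3.74). PECP1 was higher, at 18.23 ± 5.41 CPM (3.13, SE 0.34, adjusted p = 0.00102), together with AT2G01422 (4.61), AT1G75945 (3.98) and the methyltransferase gene AT5G38020 (2.48). CRC lost its call with DESeq2 (adjusted p = 0.111) and without SR45a-1a-OE replicate 1 or sr45a replicate 1, and AT5G38020 without SR45a-1a-OE replicate 1 or sr45a replicate 1 or 2. The total of 1459 became 300 and 967 without SR45a-1a-OE replicate 1 or 2 and 270 and 417 without sr45a replicate 1 or 2, and 2653 and 2310 without replicate 3 of SR45a-1a-OE or of sr45a.

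Of 21 heat shock factors and regulators 5 were higher in SR45a-1a-OE than in sr45a and 16 did not pass; all 21 values lay above 0 (7 passed when adjusted over the list alone). The median was 0.34, and the list passed in camera (adjusted p = 1.61e-04; adjusted p = 0.406 with an estimated correlation). HSFA1E was higher by 1.01 (SE 0.21, adjusted p = 0.0182), HSFA3 by 0.84 and HSFA6B by 0.83. Small heat shock proteins passed (median 0.34, adjusted p = 0.0111; adjusted p = 0.628 with an estimated correlation) except without SR45a-1a-OE replicate 1 (adjusted p = 0.267). HSP17.4B and HSP17.6A-CI were the 2 called of 18, at 0.74 and 0.85 (2 when adjusted over the list alone). Of 24 abscisic acid and dehydration genes 6 were higher and none lower (10 and 1 when adjusted over the list alone), including KIN1 (1.21, SE 0.14, adjusted p = 0.00133), GOLS2 (1.23) and LTI30 (0.91), and the list passed (adjusted p = 0.00157; adjusted p = 0.42 with an estimated correlation). Clock genes passed (median 0.25, adjusted p = 0.0111; adjusted p = 0.42 with an estimated correlation) with LHY at 1.29, PRR9 at 0.57 and LUX at 0.35 the 3 called of 19 (3 when adjusted over the list alone). Unfolded protein response genes passed downward (median −0.29, adjusted p = 0.0111; adjusted p = 0.421 with an estimated correlation), with BIP2 (−0.54) and PDIL1-1 (−0.46) the 2 called of 21 (11 lower and 1 higher when adjusted over the list alone). Other splicing factors passed upward (median 0.10, adjusted p = 0.029; adjusted p = 0.406 with an estimated correlation), with STA1 at 0.83 and AFC2 at 0.38 the 2 called of 21 (2 when adjusted over the list alone). They did not pass without SR45a-1a-OE replicate 2 (adjusted p = 0.0518) or sr45a replicate 2 (0.0671). Splits that mix the genotypes gave up to 8 lists, against the 6 here.

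The other 9 lists did not pass between SR45a-1a-OE and sr45a, with camera adjusted p from 0.1 to 0.925. SR protein genes gave 0 calls of 19 in edgeR by either adjustment, with a median of 0.08. Photosynthesis (33 genes) and flowering (3) also had 0 calls, where 5053 genes of the comparison reached an unadjusted p under 0.05. Higher and lower calls were 0 and 2 for large chaperones, 2 and 4 for detoxification, 0 and 3 for defence, 1 and 0 for flavonoid synthesis, 0 and 1 for senescence and 2 and 0 for root markers. The calls adjusted over the list alone numbered 1, 8, 3, 3, 1 and 2 in the same order. The detoxification median of 0.0126 and the test pointed up where the mean was −0.004. Of the 15 list genes named here KIN1 alone kept its call in every alternative, and the other 14 reached adjusted p between 0.0512 and 0.205 in at least 1 of them.

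SR45a-1a-OE and sr45a shared 147 changed genes against WT, 70 higher in both, 69 lower in both and 8 opposite. Lists drawn independently would share 50.01 genes, with 11.7 higher in both, 13.1 lower in both and 25.2 opposite. The same 3 WT libraries serve both comparisons, which by itself couples them. Simulated groups with no difference from WT had fold changes that correlated at 0.492 across genes, against 0.511 in the data (genes are not independent replicates). The covariance of the fold changes was 0.112 in the data and 0.0297 in the simulations. The simulations called on average 0.45 and 0.25 genes, too few to say how many shared calls the common WT libraries give. AT3G01345, AT3G05945 and AT2G01422 belong to the genes that moved the same way in both. SR45a itself, the cytokinesis syntaxin gene SYP111 (1.03 in SR45a-1a-OE and −2.48 in sr45a; within 1 Mb of SR45a) and the ferritin gene FER3 (0.49 and −0.64) were higher in SR45a-1a-OE and lower in sr45a. EARLI1 (−1.64 and 2.59), the pectin methylesterase gene ATPMEPCRB (−1.56 and 1.97), XTR6 (−1.05 and 0.68), SQE6 (−0.63 and 0.86) and WR3 (−0.35 and 0.66) were the reverse. These 8 were named after their values were seen. The overlap became 33, 23 and 57 genes without WT replicate 1, 2 or 3.

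**Figure D4:**
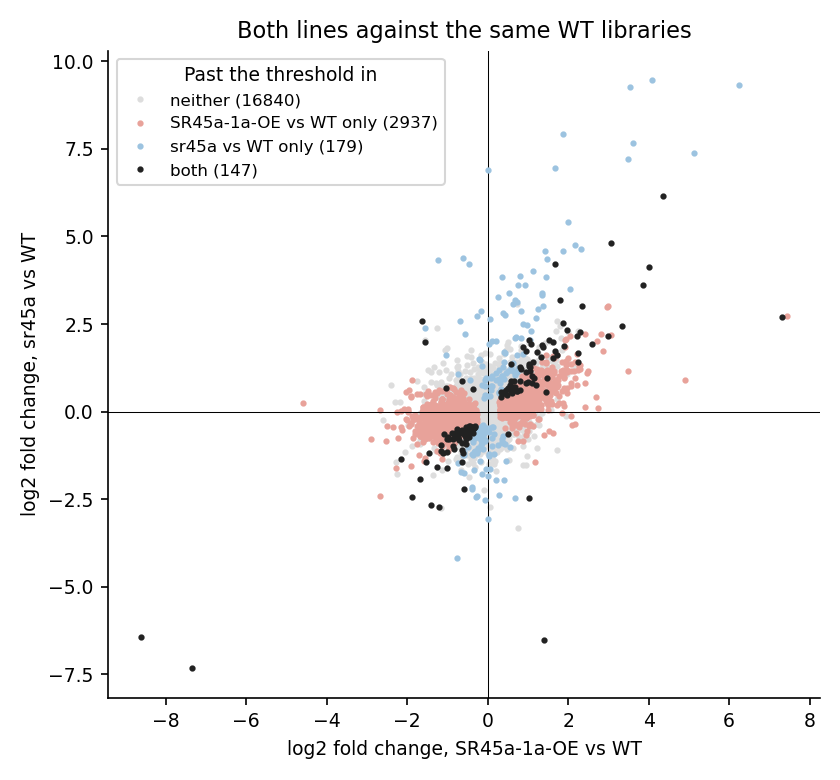
Log2 fold change of each tested gene in SR45a-1a-OE against WT (horizontal axis) and in sr45a against WT (vertical axis). Points are genes, coloured by whether they passed in neither comparison, in 1 of them or in both (147 genes); most of the 147 lie in the quadrants where both values have the same sign.

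Few single transcripts passed, and their estimates scattered more between replicates than the gene counts did. The coefficient of variation fitted by edgeR was 0.807 for transcripts and 0.138 for genes. Of 35982 annotated transcripts tested, 7 rose and 7 fell in SR45a-1a-OE against WT, 12 rose and 8 fell in sr45a against WT, and 9 were higher and 15 lower in SR45a-1a-OE against sr45a. At an unadjusted p under 0.05 there were 4312, 2642 and 3686 transcripts, and DESeq2 called 2153, 1026 and 1660. Splits that mix the genotypes gave up to 11, 13 and 14 transcripts with edgeR. The transcripts AT2G01422.1 and AT3G05945.1 rose and AT3G01345.1 fell in both genotypes against WT. ADT4 transcript AT3G44720.1 (log2 fold change −2.09, SE 0.19) and the carbonic anhydrase transcript AT4G33580.1 of BCA5 (−2.55, SE 0.17) fell in SR45a-1a-OE. The glutathione transferase transcript AT1G02930.1 of GSTF6 rose (3.05, SE 0.30) and AT5G06390.1 of FLA17 fell (−3.02, SE 0.15) in sr45a. These transcripts, apart from SR45a, were named after their values were seen. Without replicate 3 of SR45a-1a-OE the count against WT was 28. For SR45a-1a-OE against sr45a the count was 15 without SR45a-1a-OE replicate 1 and 40 without sr45a replicate 3.

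Transcript usage is the share that each transcript takes of the estimates summed over a gene's annotated transcripts. The test called 27 genes in SR45a-1a-OE and 23 genes in sr45a against WT, 11 of them in both. Both comparisons use the same 3 WT libraries, and the 11 shared genes were not set beside a value for unchanged groups. Between SR45a-1a-OE and sr45a 27 genes were called. Splits of the same 6 libraries that mix the genotypes called up to 24, 23 and 26 genes in the order of the comparisons. At an unadjusted p under 0.05 there were 468, 507 and 492 of the 7888 genes tested. With well-calibrated p-values, unchanged genes alone would pass that limit at a share of 0.05. In the protein kinase gene ATATH8 (AT2G39190) the transcript AT2G39190.1 went from 3.33 ± 1.57% of the gene in WT to 70.4 ± 1.75% in SR45a-1a-OE (adjusted p = 6.04e-04), while the gene as a whole had a log2 fold change of −0.00. In sr45a its other transcript AT2G39190.2 fell from 96.7 ± 1.57% to 24.0 ± 9.97% (adjusted p = 5.04e-04). The alcohol dehydrogenase family gene AT5G51970 used AT5G51970.1 for 55.5 ± 4.58% in WT and 100% in both other genotypes. AT3G11530.1 of the VPS55 family went from 0% in WT to 28.4 ± 12.4% in SR45a-1a-OE and 25.7 ± 14.4% in sr45a, and PPR596 lost AT1G80270.1, which took 24.7 ± 11.6% in WT, in both. A cyclic nucleotide-gated channel gene, CNGC9, used AT4G30560.3 for 56.4 ± 20.5% in sr45a, 0.0597% in WT and 0% in SR45a-1a-OE, and AT4G31880.1 of a transcriptional regulator took 100% in sr45a, 56.0 ± 4.37% in WT and 59.7 ± 8.81% in SR45a-1a-OE. In SR45a-1a-OE the major facilitator superfamily gene AT1G67300 went from 62.7 ± 6.21% to 1.47 ± 0.305% for AT1G67300.1, and ALPHA-SNAP2 from 100% to 88.4 ± 4.74% for AT3G56190.1. ECT4 (AT1G55500.2, 10.4 ± 1.198% against 0%) and AT2G26970 (AT2G26970.2, 73.5 ± 9.64% against 0%) separated SR45a-1a-OE from sr45a. The shares of exactly 0% or 100% had an SD of 0 within their group. Whether the estimation of transcripts set these extremes was not tested. Of the 13 SR protein, 13 splicing factor and 7 heat shock factor genes tested for usage, edgeR called 0 in each comparison, with at most 2 genes of a list at an unadjusted p under 0.05. limma called RS31A in SR45a-1a-OE against WT and against sr45a, and HSFA3 in SR45a-1a-OE against WT. In sr45a against WT the count was 38 or 41 without sr45a replicate 1 or 2. The median SD of the main transcript's share between replicates was 9.25, 9.64 and 9.89 percentage points in WT, SR45a-1a-OE and sr45a.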

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

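The tests of the seed, phosphate and near-SR45a patterns were chosen after the results were seen, and their lists contain genes noticed in the data. The bootstrap intervals of list medians resample genes, which are not independent, and leave out the spread between libraries.

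Transcripts with no gene identifier take 15.3–17.86% of the transcript estimates and are in none of the comparisons above. Among 17835 of them tested, 6 rose and 4 fell in SR45a-1a-OE against WT. In sr45a against WT 7 rose and 4 fell.

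Seed reserve genes were higher in sr45a. Their summed level over 16 measured genes was 78.3, 65.7 and 39.1 CPM in the sr45a libraries, 12.2, 18.3 and 6.12 in SR45a-1a-OE and 3.94, 4.32 and 4.04 in WT. Of the 16 genes 15 rose in sr45a, among them the oleosin gene OLEO1 and the late embryogenesis gene M17, while EM6 had 0.46 and did not pass. The list holds 24 genes, and only these 16 passed the count filter. Some, such as CRB and EM1 at 0 CPM in WT, passed it only through sr45a, so the tally favours rises. In SR45a-1a-OE against WT 3 of the 16 rose and 0 fell, with a median of 2.18. A general abscisic acid response is argued against by the abscisic acid and dehydration list, where 0 of 24 genes rose and 1 fell in sr45a. Adjusted over the list alone, 3 rose and 5 fell. The list median was −0.17 (95% bootstrap interval over genes −0.34 to 0). Seed coats, ungerminated seeds or delayed seedlings in the sr45a samples stay open and cannot be told apart from a change within the seedlings. Of 12 listed members not noticed beforehand only 4 passed the count filter, and 75% of these 4 rose. The filter favours genes that are high in sr45a, so this share cannot decide.

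Phosphate starvation genes were lower in sr45a, 18 of 24 past the threshold, with a median of −1.21. Of the 16 measured members not noticed beforehand 10 fell and 0 rose, with a median of −1.09. Their summed level was 861, 775 and 689.6 CPM in sr45a, 1331, 1532 and 1110 in SR45a-1a-OE and 1431, 1674 and 1813 in WT, with AT4 at −1.95, SPX3 at −3.08 and PHT1.4 at −1.62. A smaller share of root in the sr45a samples is argued against as the whole cause. The median of the root markers lay above that of the whole phosphate list by 1.17 (0.57 to 1.81). The root median was −0.04, against −1.09 for the phosphate genes not noticed beforehand. A graded response to the level of SR45a would raise these genes in SR45a-1a-OE, but 0 of the 24 rose and 8 fell against WT. The median there was −0.37 (−0.57 to −0.17), not above 0, and −0.44 for the genes not noticed beforehand. The same 3 WT libraries serve both comparisons, which couples them, so these values cannot decide on a graded response. Against sr45a, 15 of the 24 genes were higher in SR45a-1a-OE and 0 lower, with a median of 0.89. A difference in phosphate supply or uptake between the plates or plants stays open, as does an effect of losing SR45a, and neither was tested.

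Within 1 Mb of SR45a on chromosome 1, 12 of 471 tested genes passed in sr45a against WT, 2.55% against 1.59% elsewhere, and 9 of the 12 were lower, among them AT1G08310 and SYP111. The odds ratio was 1.61 (0.819 to 2.89, Fisher exact p = 0.134). In SR45a-1a-OE the odds ratio of the same window was 0.979 (0.748 to 1.27). Sequence linked to the mutated locus may add calls there, but with 12 genes it cannot be told apart from chance, nor can a regional effect in both genotypes. No biological explanation was tested for this window.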

How the results depend on the processing

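The alternatives with transcripts that have no gene and with estimates divided by 4 were chosen after the results were seen; the others were planned. The SR45a level kept its direction and call in all 14 alternatives of each comparison, with log2 fold changes of 1.33 to 1.44 in SR45a-1a-OE (highest adjusted p 0.0427), −7.04 to −6.08 in sr45a (1.86e-04) and 7.42 to 8.42 between them (5.08e-05). Of 100 called results of named genes, where a gene counts once per comparison, 0 changed sign; 73 stayed called in all settings that keep every library and 55 also when any library was left out. With the replicate number as a block the genes numbered 1842, 193 and 575 in the order SR45a-1a-OE against WT, sr45a against WT and SR45a-1a-OE against sr45a, the overlap 65, the transcripts 2 in each comparison and the usage genes 13 (first) and 17 (last). The numbers do not pair the samples: deviations of libraries with the same number correlated at −0.331 to 0.186 across genes, and not every sample correlated best with its own number. With an estimated inter-gene correlation camera called 0, 0 and 0 lists. DESeq2 gave 704 genes in sr45a, an overlap of 350 and 2153, 1026 and 1660 transcripts. Fits of only the 6 libraries compared gave 532 genes in sr45a and 557 between SR45a-1a-OE and sr45a. Requiring a log2 fold change of 1 left 680, 179 and 485 genes by construction. limma diffSplice gave 46 usage genes in sr45a. Leaving out 1 library gave 975 to 3944, 106 to 215 and 270 to 2653 genes; 12 to 28, 14 to 28 and 15 to 40 transcripts; 18 to 29, 20 to 41 and 24 to 38 usage genes; 3 to 5, 2 to 5 and 5 to 9 lists; and an overlap of 23 to 57. Genes numbered 3944 in SR45a-1a-OE without its replicate 3 and 215 in sr45a without its replicate 3, the libraries that stood apart. Lists in sr45a numbered 5 without WT replicate 2 or sr45a replicate 3. From FPKM with limma 35.6% of the genes called in SR45a-1a-OE rose, against 44% in the main test. Values that had not passed changed sign for HSP22.0 (−0.14 without WT replicate 1, otherwise up to 0.1012), CHS (0.0019 without WT replicate 2, down to −0.1734), SR34 (0.0244 without SR45a-1a-OE replicate 2, down to −0.1006), AOS (−0.0017 without sr45a replicate 1, up to 0.134) and ROF2 (−0.147 without sr45a replicate 3, up to 0.2149). Fewer libraries explain part of the lower counts; otherwise the cause was not tested. The effect of depth was not tested. In simulated data with the spread of these transcript estimates edgeR recovered 3% of 4-fold and 47% of 32-fold changes.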

Other observations

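The tests of process terms were chosen after the results were seen, and their 110 terms come from the annotation (one-sided Fisher exact tests against 8740 tested genes that have a term, Benjamini-Hochberg adjusted). Genes whose annotation gives only a number of processes have no term here, so the counts need not cover all genes of a process. The tests treat genes as independent, although the estimated inter-gene correlation of a fixed list reached 0.55. Their p-values may therefore be too small. The splits of the samples were planned.

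Growth and cell wall genes were over-represented among the genes that fell in SR45a-1a-OE. Carbohydrate metabolic process held 48 of 239 genes (Fisher exact, adjusted p = 6.79e-04), among them XTR6 (−1.05) and XTH8 (−1.39), which act on xyloglucan, and BGLU11 (−1.19). Cell wall modification held 9 of 29 (Fisher exact, adjusted p = 0.0391), with the pectin methylesterase genes ATPMEPCRD (−1.67), PME44 (−1.23) and PME5 (−0.94). Unidimensional cell growth held 13 of 44 (Fisher exact, adjusted p = 0.0147), with XTH4 (−0.88), the peroxidase gene PRXCB (−0.91) and the wall-associated kinase gene WAK2 (−1.51). Signalling through receptor kinases held 25 of 107 (Fisher exact, adjusted p = 0.00479), the response to cyclopentenone 13 of 50, and microtubule-based movement 12 of 45, with the kinesin gene ATK2 at −0.53. Among the genes that rose, protein folding held 30 of 203 where 12.9 were expected (Fisher exact, adjusted p = 0.0012), response to stress 12 of 69 and lipid transport 11 of 57 (Fisher exact, adjusted p = 0.0415 for both). The pentose-phosphate shunt held 6 of 21 (Fisher exact, adjusted p = 0.0415), with PGL5 (2.23), PGL4 (1.06) and FBA1 (0.79).

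In sr45a, genes of lipid transport (8 of 57) were over-represented among those that rose (Fisher exact, adjusted p = 2.74e-05). They include the seed albumin genes SESA1, SESA2 and SESA5, which are on the seed reserve list already described. The term also passed among genes that rose in SR45a-1a-OE, and AT4G15160 and AT3G18280 rose in both. Genes of the abscisic acid stimulus were over-represented among those that rose in sr45a as well (8 of 71, Fisher exact, adjusted p = 7.72e-05). At least 4 of these 8, CRA1, CRB, CRC and EM1, are the seed reserve genes already described. The fixed abscisic acid and dehydration list, which holds none of these 4, had a median of −0.17. Embryo development ending in seed dormancy held 10 of 194 (Fisher exact, adjusted p = 0.00281). The response to phosphate starvation held 6 of 22 among those that fell (Fisher exact, adjusted p = 7.24e-06). These were the root marker PHT1.1 and PHT1.2, SQD1, SQD2, PHF1 and PAP12 of the phosphate list already described. Between SR45a-1a-OE and sr45a, responses to cyclopentenone (12 of 50), cell wall modification (8 of 29), carbohydrate metabolism (27 of 239), salt stress (25 of 234), proteolysis (27 of 271) and unidimensional cell growth (8 of 44) were over-represented among genes lower in SR45a-1a-OE (Fisher exact, adjusted p of 0.00138, 0.00691, 0.0111, 0.0313, 0.0456 and 0.0458). No term passed among genes higher there.

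Of the 10 ways to split 6 libraries into 3 and 3, no share under 0.05 can be had. Every other split puts both genotypes in each group. A true difference between genotypes then widens the spread within groups and partly remains between them. The counts of the other splits are therefore not values for groups with no difference. For genes, 1 split, the real one, gave as many in SR45a-1a-OE against WT (3084; highest other 0), in sr45a against WT (326; highest other 0) and between SR45a-1a-OE and sr45a (1459; highest other 150). For transcripts it was 1 of 10 as well, with 14, 20 and 24 in the real splits and 11, 13 and 14 in the highest others. For usage 1, 2 and 1 splits gave as many genes as the real 27, 23 and 27, and the highest others gave 24, 23 and 26. For lists 7, 3 and 4 splits gave as many as the real 3, 3 and 6, and the highest others gave 7, 3 and 8.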
